A study of Homo sapiens with 18 samples.

How the data were processed

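Total RNA of 2 human B-cell lymphoma lines, OCI-Ly3 and Daudi, was hybridised in a single colour to whole human genome oligonucleotide arrays after treatment with 1 of 3 siRNAs, directed at p100, p105 or luciferase. Each of the 6 groups held 3 arrays, 18 in all, and groups and replicate numbers were taken from the sample titles. RNA was isolated with a spin-column kit (Qiagen RNeasy mini) and labelled with Cy3 by the Agilent standard procedure, per the labels' protocols. Spots were quantified with Agilent Feature Extraction 9.5.3.1 on array design 014850, with probe positions on genome build hg17, per the file headers. The deposited scanner tables give a linear intensity for each spot: a processed signal that the software had background-subtracted and detrended within the array, and the unprocessed mean signal and local background, per the file headers. No step between arrays had been applied to these intensities.

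The authors also deposited a table of processed values, whose scale, centring and direction are not given in the sources used here. From the values, these are on a log2 scale and are not background-subtracted, since each column correlated with log2 of the mean spot intensity of its own array at a lowest r of 0.9976 across probes. The 9 columns of each line share one distribution, which is quantile normalization within a line, with column medians of 6.65 in OCI-Ly3 and 5.79 in Daudi. Genes were not centred, and higher values are brighter spots. This deposited log2 table served as an alternative, and all of its columns were mapped to samples.

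For the main values, log2 of the processed signal was taken and the 75th percentile of the non-control spots of each array was subtracted. Control spots and spots marked as outliers were left out, saturated spots were kept, and spots of the same probe were averaged. The arrays carry 43376 non-control spots and 41000 probes. Gene symbols were updated through a RefSeq table: 23845 probes matched by accession, 2018 by symbol and 966 by an older symbol, and 14171 kept the name in the files. Each gene was represented by its probe with the highest mean over all 18 arrays, giving 30986 genes or names. Probes were tested in a line where they were well above background on all 3 arrays of at least 1 of its groups, which left 20658 genes in OCI-Ly3 and 14297 in Daudi, 13109 of them in both.

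Each line was fitted on its own with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes over its 9 arrays), with Benjamini-Hochberg adjustment over genes. A line was fitted alone, against luciferase siRNA and at an adjusted p of 0.001, because the design text names linear models with these choices. Genes with an adjusted p under 0.05 were counted as a second, looser level. Differences between lines were tested as interaction contrasts in a fit of all 18 arrays, over 21846 genes. Overlaps were set against the number that independent lists would share and against 20 simulations of unchanged groups that share control arrays. All 9 arrays of a line were drawn there as independent noise with each gene's residual SD, so no slide effect was simulated. All p-values are two-sided, Fisher's exact test of overlaps included. Log2 fold changes are given ± SE, with 3 arrays in each group.

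A probe that was not well above background on any array of a group has only a bound there. Its change is given as at least N-fold: the mean of the brighter group over all 3 arrays, against the mean of the dimmer group in which each array contributes the higher of the probe's own value and the lowest signal among probes well above background on that array. The bound refers to that probe and carries the adjusted p of the fit. The largest rises and falls were chosen by fitted change, so for such probes the choice rests on values near background.

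There were 33 gene lists, written before the data were examined. They covered the NF-kB family, NF-kB targets, homologous recombination, the Fanconi pathway, end joining, mismatch repair, base and nucleotide excision repair, damage checkpoints, p53 targets, DNA replication, G2/M, G1/S, class switching with somatic hypermutation, apoptosis inhibitors and inducers, B cell receptor signalling, germinal centre and plasma cell programmes, interferon response, unfolded protein response, amino acid response, cholesterol synthesis, oxidative phosphorylation, glycolysis with hypoxia, ribosome biogenesis, histones, RNA interference and MHC class II. The other 4 held markers of T cells, myeloid cells, erythroid cells with platelets, and fibroblasts with epithelium. Lists with at least 5 measured genes were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison and a threshold of 0.05. Camera with an estimated correlation and fry were alternatives.

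Genes are named by a rule fixed at the same time: the targets NFKB2 and NFKB1, the 8 largest rises and 8 largest falls past 0.001 with groups that do not overlap and with a gene symbol, filled by smallest p under 0.05 where fewer passed, up to 10 common genes per direction, up to 4 past members per list, and 4 per direction for the contrast of the siRNAs and for differences between lines. Genes named outside the rule are said to be so, and some genes that the rule picks are not reported here. Probe disagreements in sign past 0.05 are stated where they occur.

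The arrays lay on 5 slides and were scanned on 1 date. The first slide held the OCI-Ly3 p105 arrays and p100 replicate 1, and the second held p100 replicates 2 and 3 with luciferase replicates 1 and 2. The third held OCI-Ly3 luciferase replicate 3 with the Daudi p105 arrays, the fourth the Daudi p100 arrays with luciferase replicate 1, and the fifth Daudi luciferase replicates 2 and 3. Slide was therefore fitted as a fixed block where the groups could still be separated. Otherwise it was a random block, which cannot remove a slide effect from groups that lie on separate slides. In a fit within 1 slide, an arm of 1 array is assumed to vary like the other arm. For the slides that held arrays of both groups, the fixed block and the fit within the slide give the same change, so they are not separate checks. Alternatives chosen beforehand were normexp background correction (offset 50), quantile normalization, no filter on dim probes, an adjusted p of 0.05, a minimum fold of 1.5, a replicate block, a slide block, 1 fit over 18 arrays, only the 6 arrays compared, the mean of a gene's probes, the authors' values, trended and robust moderation, and leaving out each array. Chosen after seeing the data were a percentile over probes well above background on all 9 arrays of a line, normexp without spots whose local background exceeded their signal by more than 100 units, values within single slides, and slide as a block for lists. A block for scan date could not be fitted with 1 date.

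The procedure was tested on simulated data with 200 changed genes. For OCI-Ly3 p100 siRNA over 20658 genes, 23.9%, 53.7% and 84.8% of genes changed by 1, 2 and 4 log2 units were called at 0.001, and 0 unchanged genes were. For Daudi p100 siRNA over 14297 genes the shares were 0%, 17.9% and 87.9%. For the p100 interaction over 21846 genes they were 0%, 23.9% and 84.8%. Arrays give no read depth, so the number of arrays limits the precision. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.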

Results

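Gene expression was compared in 2 human B-cell lymphoma lines after treatment with small interfering RNAs (siRNAs) against precursors of NF-kB transcription factors. OCI-Ly3 is a diffuse large B-cell lymphoma line of the activated B-cell type, in which NF-kB signalling is constitutively active. Daudi is a Burkitt lymphoma line that carries Epstein-Barr virus. The siRNAs were directed at p100, the NFKB2 product that is processed to p52, at p105, the NFKB1 product that is processed to p50, or at luciferase, a control with no human transcript to target. The study asked which genes responded to each siRNA in each line, and which responded in both, under a title that ties NF-kB to genomic instability. Each of the 6 groups held 3 arrays. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

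Signal differed between the lines. The 75th percentile of the processed signal lay between 469 and 656 units on the OCI-Ly3 arrays and between 24.2 and 64.0 on the Daudi arrays. Between 64.3% and 73.5% of spots were well above background in OCI-Ly3 and between 36.2% and 64.8% in Daudi. The median residual SD of the fit was 0.20 log2 units in OCI-Ly3 and 0.41 in Daudi, so smaller changes could be detected in OCI-Ly3. Over 6707 pairs of probes for the same gene, Spearman's rho was 0.642 in OCI-Ly3 and 0.236 in Daudi.

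**Figure D1:**
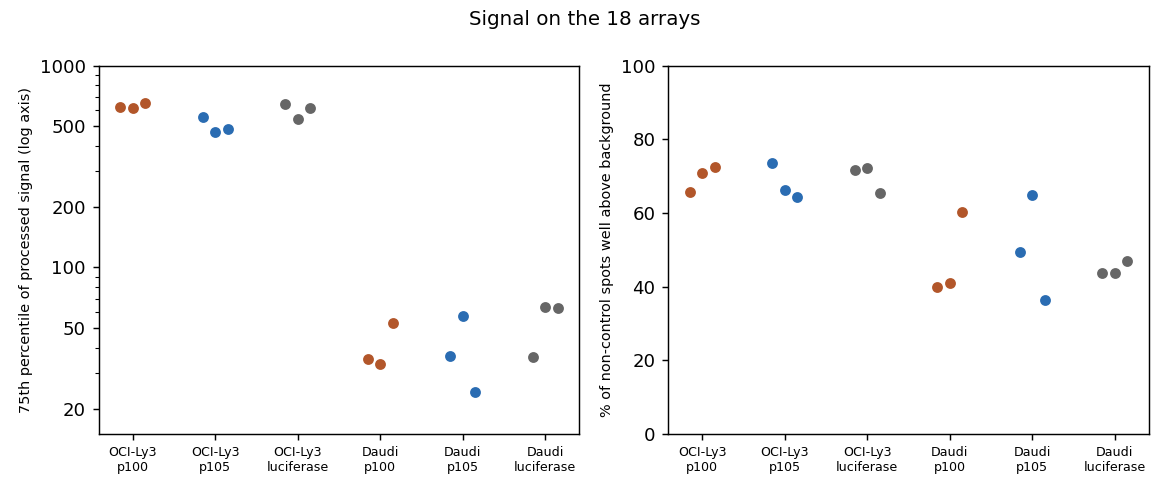
Each point is 1 array, grouped by line and siRNA: 1 panel gives the 75th percentile of the processed signal in intensity units on a log axis, the other the percentage of non-control spots well above background. All 9 Daudi arrays lie at or below 64.0 units, while all 9 OCI-Ly3 arrays lie at or above 469 units.

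The targeted transcripts were examined first. In Daudi, the NFKB2 probe (chromosome 10, 104151043 to 104151219, hg17) read 3.42 ± 0.33 log2 units (SD, n = 3) with p100 siRNA, 3.89 ± 0.68 with p105 siRNA and 5.11 ± 0.12 with luciferase siRNA, relative to each array's 75th percentile. NFKB2 fell by 1.69 ± 0.35 with p100 siRNA (limma adjusted p = 0.0164), to 0.311 of the luciferase level, and by 1.21 ± 0.35 with p105 siRNA (adjusted p = 0.0217). The NFKB1 probe (chromosome 4, 103895057 to 103895116, hg17) fell by 0.99 ± 0.31 with p105 siRNA in Daudi (adjusted p = 0.0312), while its difference of -0.73 ± 0.31 with p100 siRNA did not pass (adjusted p = 0.246). In OCI-Ly3 neither target was called lower under its own siRNA: NFKB2 differed by -0.37 ± 0.20 on the arrays labelled p100 siRNA (adjusted p = 0.297) and NFKB1 by 0.05 ± 0.09 on the arrays labelled p105 siRNA (adjusted p = 0.732). NFKB2 rose by 1.08 ± 0.20 on the OCI-Ly3 arrays labelled p105 siRNA (adjusted p = 0.00569), and NFKB1 differed by 0.19 ± 0.09 on those labelled p100 siRNA (adjusted p = 0.262). Where the siRNAs bind relative to these probes is not given in the sources used here, so the groups are named below as p100-labelled and p105-labelled arrays.

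**Figure D2:**
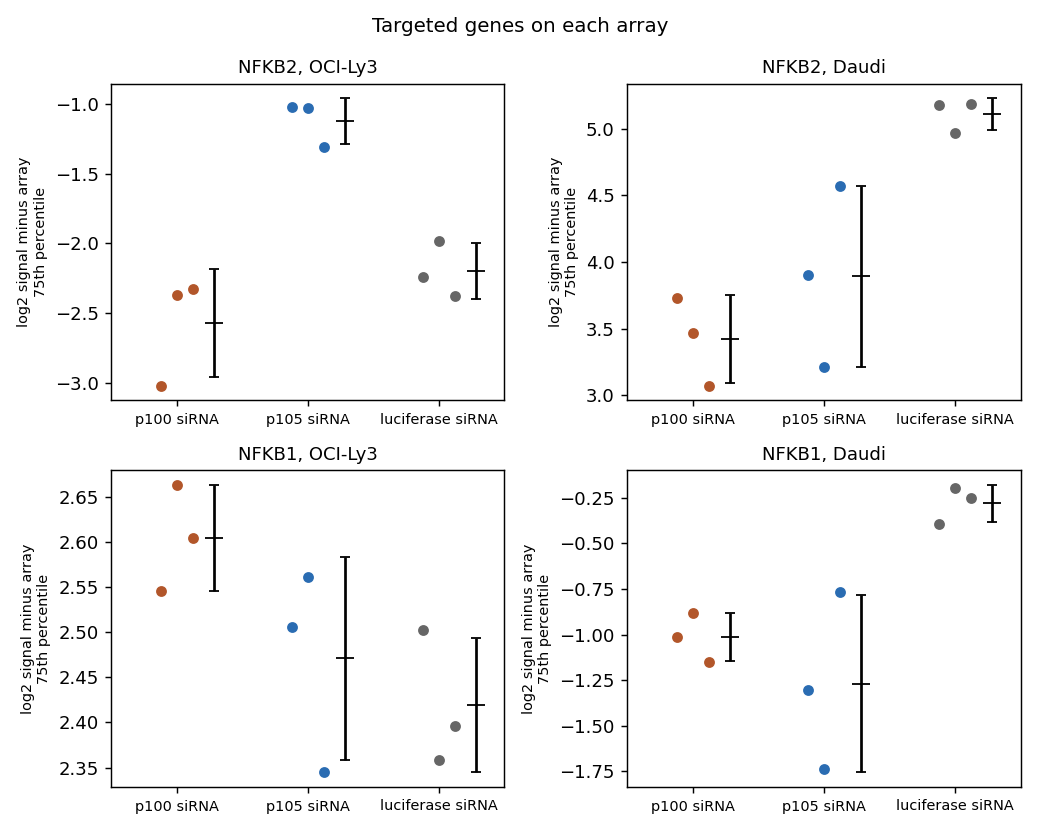
Log2 signal of the NFKB2 and NFKB1 probes relative to each array's 75th percentile, in 4 panels with separate vertical axes for each probe and line; points are arrays and bars are the mean ± SD of 3. NFKB2 in Daudi drops from 5.11 with luciferase siRNA to 3.42 with p100 siRNA, while NFKB1 in OCI-Ly3 stays between 2.42 and 2.60 in all groups.

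On the p100-labelled OCI-Ly3 arrays, genes of ribosome biogenesis, DNA replication and protein folding in the endoplasmic reticulum stood above the luciferase arrays, and genes of cholesterol synthesis and p53 targets stood below. Camera passed 9 lists. Of the 10 splits of the 6 arrays, the real one included, 3 passed at least as many (highest other 15). Of 28 ribosome biogenesis genes, 16 rose and 0 fell at an adjusted p under 0.05, and 22 rose adjusted over the list alone. Their median log2 change was 0.52 (camera adjusted p = 9.46e-14, adjusted p = 0.2005 with an estimated correlation). They included UTP20 (1.05 ± 0.14), MRTO4 (0.97 ± 0.13), PES1 (0.92 ± 0.12) and RRP9 (0.79 ± 0.12), which act in assembly of the ribosomal subunits. Of 36 replication genes 7 rose and 0 fell (12 and 0 adjusted over the list alone), with MCM5 at 0.75 ± 0.12, ORC5 at 0.58 ± 0.08, POLA2 at 0.56 ± 0.12 and MCM4 at 0.54 ± 0.14. Their median change was 0.25 (camera adjusted p = 0.000163, adjusted p = 0.365 with an estimated correlation). Of 22 unfolded protein response genes 8 rose and 0 fell (11 and 1 adjusted over the list alone), among them the chaperones HSPA5 (0.95 ± 0.17), DNAJB11 (0.84 ± 0.13) and CALR (0.60 ± 0.13) and the transcription factor XBP1 (0.92 ± 0.17). For that list the median was 0.27 (camera adjusted p = 0.00136, adjusted p = 0.196 with an estimated correlation).

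In the same comparison 4 of 22 cholesterol synthesis genes fell and 0 rose (7 and 0 adjusted over the list alone), including INSIG1 (-1.05 ± 0.18), HMGCS1 (-0.78 ± 0.20) and FDFT1 (-0.65 ± 0.17). The median of the list was -0.36 (camera adjusted p = 0.00136, adjusted p = 0.860 with an estimated correlation). Of 22 p53 targets 9 fell and 0 rose, while adjusted over the list alone 9 fell and 2 rose (median -0.14, camera adjusted p = 0.0344, adjusted p = 0.365 with an estimated correlation). These included TP53INP1 (-1.43 ± 0.20), TP53I3 (-0.83 ± 0.16), the growth arrest gene GADD45A (-0.82 ± 0.14) and the death receptor TNFRSF10B (-0.58 ± 0.10). In the amino acid response, 3 of 18 genes fell and 0 rose (4 and 0 adjusted over the list alone, median -0.25, camera adjusted p = 0.0172, adjusted p = 0.365 with an estimated correlation). The 3 were VLDLR (-1.76 ± 0.42, well above background on 2 of 3 p100-labelled arrays), CTH (-1.16 ± 0.13) and DDIT4 (-0.74 ± 0.20). Of 20 genes of class switching and somatic hypermutation, 4 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.0172, adjusted p = 0.365 with an estimated correlation). Its members past 0.05 included the elongation factor SUPT5H (0.60 ± 0.11), TRIM28 (0.45 ± 0.08), the endonuclease APEX1 (0.43 ± 0.10) and, in the other direction, the polymerase POLI (-0.74 ± 0.19). Oxidative phosphorylation had 6 rises among 35 genes and 0 falls (7 and 0 adjusted over the list alone, median 0.18, camera adjusted p = 0.0172, adjusted p = 0.922 with an estimated correlation). Rises were led by NDUFS3 at 0.54 ± 0.10 and SDHD at 0.50 ± 0.12. Of 14 histone genes 2 rose and 0 fell, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.0344, adjusted p = 0.859 with an estimated correlation): H2AC18 (1.33 ± 0.26) and H2BC12 (1.27 ± 0.12).

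NF-kB target genes did not pass as a list on these arrays (3 of 36 rose and 4 fell, 5 and 5 adjusted over the list alone, camera adjusted p = 0.724). TNF rose by 2.43 ± 0.50 and the superoxide dismutase SOD2 by 0.68 ± 0.12, while the apoptosis inhibitor BIRC3 fell by 0.71 ± 0.14 and lymphotoxin beta, LTB, by 0.60 ± 0.13. The list members CD44 and CCND2, named outside the rule, differed within the p100-labelled group. CD44 read 0.90 and 0.19 on replicates 2 and 3 and -6.01 on replicate 1 (luciferase arrays -3.72 to -3.13). CCND2 read -0.04 and -0.24 on replicates 2 and 3 and -5.66 on replicate 1 (luciferase arrays -4.92 to -4.37). Of 28 NF-kB family genes, 0 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.670): RELB, the partner of p52 (-0.61 ± 0.14), and the inhibitor NFKBIA (-0.46 ± 0.11). The repair lists did not pass either, with camera adjusted p = 0.358 for homologous recombination, 0.670 for the Fanconi pathway, 0.369 for end joining, 0.690 for mismatch and nucleotide excision repair, and 0.806 for base excision repair.

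A single gene passed an adjusted p of 0.001 on the p100-labelled OCI-Ly3 arrays, the pseudogene SIGLEC17P, at least 2.07-fold lower (limma adjusted p = 0.000775). At the looser level 1130 genes rose and 1387 fell, and 6868 genes (33.2%) had groups that did not overlap, where chance gives 10%. By the smallest p, rises were led by the histone H2BC12, the membrane estrogen receptor GPER1 (1.42 ± 0.14), IRF2BP1 (0.93 ± 0.09), and EEPD1 (1.14 ± 0.12). They went on with the splicing factor SRSF6 (1.06 ± 0.12), BRMS1 (0.74 ± 0.08), the RNA polymerase subunit POLR1C (0.77 ± 0.09) and the importin IPO4 (0.87 ± 0.10), with adjusted p between 0.00368 and 0.00479. Falls were led by the homeobox gene MEIS1 (-2.28 ± 0.14), RAB37 (-2.08 ± 0.16), NDRG4 (-1.44 ± 0.11), and PCSK4 (-2.24 ± 0.19). Further falls were MYH11 (-1.14 ± 0.09), the natural killer receptor gene KLRC3 (-2.36 ± 0.20, above background on 1 of 3 p100-labelled arrays) and NOTCH2NLA (-1.52 ± 0.13), with adjusted p between 0.00118 and 0.00336. With slide as a block 2 other genes passed 0.001, both rises, and within the slide that held 2 arrays of each group 0 genes passed 0.001 and 137 passed 0.05. Log2 changes within the slide correlated at r = 0.932 with those of all 6 arrays, of which these 4 are part. Under that block, whose changes are those within the slide, all 9 lists kept their sign and 7 stayed past 0.05, the exceptions being class switching (adjusted p = 0.0607) and oxidative phosphorylation (adjusted p = 0.184). Tested on the arrays of the slide alone, p53 targets (adjusted p = 0.0994) did not pass either. The authors' values gave 16 rises and 83 falls at 0.001, normexp without spots of high local background 30 and 68, and without p100 replicate 1 the count was 8, against 0 without any other array. At 19 genes replicate 1 lay at least 8-fold below both other p100-labelled arrays.

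On the p105-labelled OCI-Ly3 arrays, NF-kB target genes stood above the luciferase arrays, and genes of ribosome biogenesis, mitosis, DNA replication, homologous recombination and mismatch repair stood below. Camera passed 14 lists, while another of the 10 splits of these arrays passed 13. Of 36 NF-kB targets 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 change of 0.49 (camera adjusted p = 0.000167, adjusted p = 0.315 with an estimated correlation). Among them LTB rose by 3.34 ± 0.13, TNF by 2.44 ± 0.50, the death receptor FAS by 2.39 ± 0.12 and the chemokine CCL3 by 1.76 ± 0.32. In the NF-kB family list 12 of 28 genes rose and 6 fell (14 and 6 adjusted over the list alone, camera adjusted p = 0.0795). Log2 changes were NFKB2 at 1.08 ± 0.20, RELB at 1.04 ± 0.14, BCL3 at 0.95 ± 0.14 and the deubiquitinase CYLD at 0.78 ± 0.12. Ribosome biogenesis moved against its direction on the p100-labelled arrays: of 28 genes 24 fell and 1 rose (25 and 1 adjusted over the list alone), including RRP9 (-1.46 ± 0.12), RRP12 (-1.28 ± 0.14), NOP2 (-1.26 ± 0.14) and the helicase DDX21 (-1.18 ± 0.18). Their median was -0.77 (camera adjusted p = 5.57e-11, adjusted p = 0.213 with an estimated correlation).

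Cell cycle genes were lower on the p105-labelled OCI-Ly3 arrays. Of 35 G2/M and mitosis genes 26 fell and 0 rose, the same counts as adjusted over the list alone (median -0.45, camera adjusted p = 7.90e-09, adjusted p = 0.157 with an estimated correlation). They included the spindle checkpoint kinase BUB1B (-0.99 ± 0.12), the transcription factor FOXM1 (-0.97 ± 0.10), CENPF (-0.95 ± 0.14) and the centromeric histone CENPA (-0.83 ± 0.10). Of 36 DNA replication genes 13 fell and 2 rose, also when adjusted over the list alone (median -0.26, camera adjusted p = 0.000167, adjusted p = 0.315 with an estimated correlation). They included POLA1 (-0.91 ± 0.11), ORC5 (-0.89 ± 0.08), POLE2 (-0.82 ± 0.09) and the helicase subunit MCM7 (-0.76 ± 0.09). Of 24 G1/S regulators 8 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.28, camera adjusted p = 0.0255, adjusted p = 0.315 with an estimated correlation). The member that rose was the cyclin-dependent kinase inhibitor CDKN1B (1.36 ± 0.30), while CDK6 (-1.03 ± 0.17), E2F4 (-0.93 ± 0.18) and E2F2 (-0.90 ± 0.09) fell.

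Of 6 DNA repair lists 3 passed as lower on the p105-labelled OCI-Ly3 arrays. They are not separate findings, since the lists share members. BRCA2 is in the homologous recombination and Fanconi lists, EXO1 in homologous recombination and mismatch repair, and PCNA and POLD1 in mismatch repair and DNA replication. Of 34 homologous recombination genes 13 fell and 2 rose (21 and 2 adjusted over the list alone, median -0.33, camera adjusted p = 0.000167, adjusted p = 0.315 with an estimated correlation). XRCC2 fell by 1.44 ± 0.20, the polymerase POLQ by 0.87 ± 0.14 and RPA3 by 0.74 ± 0.17. Of 18 Fanconi genes 7 fell and 1 rose, also when adjusted over the list alone (median -0.24, camera adjusted p = 0.0118, adjusted p = 0.315 with an estimated correlation). Log2 changes were FANCA at -1.22 ± 0.15, BRCA2 at -0.66 ± 0.16, FANCC at 0.68 ± 0.16 and the nuclease gene FAN1 at least 1.91-fold lower. Of 15 mismatch repair genes 7 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.41, camera adjusted p = 0.00316, adjusted p = 0.320 with an estimated correlation). Among these were RFC3 (-0.63 ± 0.10), EXO1 (-0.59 ± 0.09), PMS2 (-0.58 ± 0.11) and RFC2 (-0.57 ± 0.12). In the checkpoint list 11 of 26 genes fell and 2 rose (13 and 2 adjusted over the list alone, median -0.24, camera adjusted p = 0.00566, adjusted p = 0.315 with an estimated correlation). There the kinase ATM rose by 0.9996 ± 0.15, while its relative ATR fell by 0.73 ± 0.13, HUS1 by 0.77 ± 0.10 and the phosphatase CDC25A by 0.68 ± 0.10. Camera adjusted p was 0.176 for end joining, 0.858 for base excision repair and 0.274 for nucleotide excision repair, the last 2 with medians above 0 (0.06 and 0.13).

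Metabolic, stress and B-cell lists also moved on the p105-labelled OCI-Ly3 arrays. Of 22 unfolded protein response genes 14 fell and 1 rose, also when adjusted over the list alone (median -0.47, camera adjusted p = 0.000167, adjusted p = 0.117 with an estimated correlation). PDIA4 (-1.18 ± 0.09) and DDIT3 (-1.13 ± 0.09) fell, ATF3 was at least 3.40-fold lower, and XBP1 rose by 0.95 ± 0.17. Of 18 amino acid response genes 9 fell and 0 rose (10 and 0 adjusted over the list alone, median -0.50, camera adjusted p = 0.00130, adjusted p = 0.225 with an estimated correlation). Its members past 0.05 included the transporter SLC7A5 (-1.56 ± 0.19), PSAT1 (-1.26 ± 0.16), CBS (-1.02 ± 0.25) and VLDLR (-1.73 ± 0.42, above background on 1 of 3 p105-labelled arrays). Of 25 glycolysis and hypoxia genes 15 rose and 3 fell (16 and 4 adjusted over the list alone, median 0.41, camera adjusted p = 0.00255, adjusted p = 0.315 with an estimated correlation). They included the aldolase ALDOC (3.33 ± 0.20), PFKFB4 (1.91 ± 0.24), NDRG1 (1.64 ± 0.27) and P4HA1 (1.26 ± 0.21). Of 16 MHC class II genes 8 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.43, camera adjusted p = 0.00908, adjusted p = 0.340 with an estimated correlation). Rises were led by HLA-DPB1 (0.89 ± 0.14) and HLA-DMA (0.78 ± 0.08). Of 19 germinal centre genes 7 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.33, camera adjusted p = 0.0345, adjusted p = 0.315 with an estimated correlation). LMO2 (3.67 ± 0.35) and SERPINA9 (1.82 ± 0.16) rose, and the methyltransferase EZH2 fell by 1.03 ± 0.11. B cell receptor signalling (7 of 26 rose, 3 fell, camera adjusted p = 0.0795), plasma cell genes (5 of 12 rose, 1 fell; 0.274), apoptosis inhibitors (4 of 14 rose, 2 fell; 0.237) and apoptosis inducers (6 of 25 rose, 2 fell; 0.530) did not pass.

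In total 360 genes rose and 372 fell at an adjusted p of 0.001 on the p105-labelled OCI-Ly3 arrays, and 3499 rose and 3108 fell at 0.05. The groups did not overlap at 9909 genes (48.0%), against 10% by chance. The largest rises were NLRP4 (4.32 ± 0.36, above background on 2 of 3 luciferase arrays), LMO2, GPER1 (3.52 ± 0.14), the collagen cross-linking enzyme LOXL2 (3.34 ± 0.11), LTB, ALDOC, the dipeptidase DPEP2 (3.05 ± 0.18) and TESMIN (at least 2.19-fold), with limma adjusted p from 5.25e-06 to 0.000381. The largest falls all ended below background on the p105-labelled arrays: WSB2 (at least 8.09-fold), PXDNL (7.06-fold), osteopontin SPP1 (5.02-fold), ADGRA3 (4.90-fold), SCHIP1 (4.69-fold), FOXJ2 (4.66-fold), SAMSN1 (4.12-fold) and the interferon-induced SAMD9L (3.98-fold), each as a lower bound and with adjusted p from 2.73e-05 to 0.000296. No slide held both p105-labelled and luciferase arrays of OCI-Ly3, so no within-slide value could be had, and with slide as a block the count at 0.001 dropped from 732 to 3. That block links the slides only through p100-labelled replicate 1 against replicates 2 and 3, so its values rest on that array. Under that block all 14 lists kept their sign and 11 stayed past 0.05, the others being glycolysis (adjusted p = 0.0973), MHC class II (0.520) and germinal centre genes (0.363). Under the same block 2 further lists passed, both higher: myeloid markers (median 0.90, adjusted p = 0.0173) and erythroid and platelet markers (median 0.82, adjusted p = 0.0172). Without the block their medians were 0.41 and 0.44 and neither passed. With dim markers included, replicate 1 lay below the lower of replicates 2 and 3 by medians of 0.864 and 0.712 in these lists. Leaving out any array lowered the count, to 102, 68 and 157 without p105 replicates 1, 2 and 3 and to 59, 181 and 123 without luciferase replicates 1, 2 and 3.

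**Figure D3:**
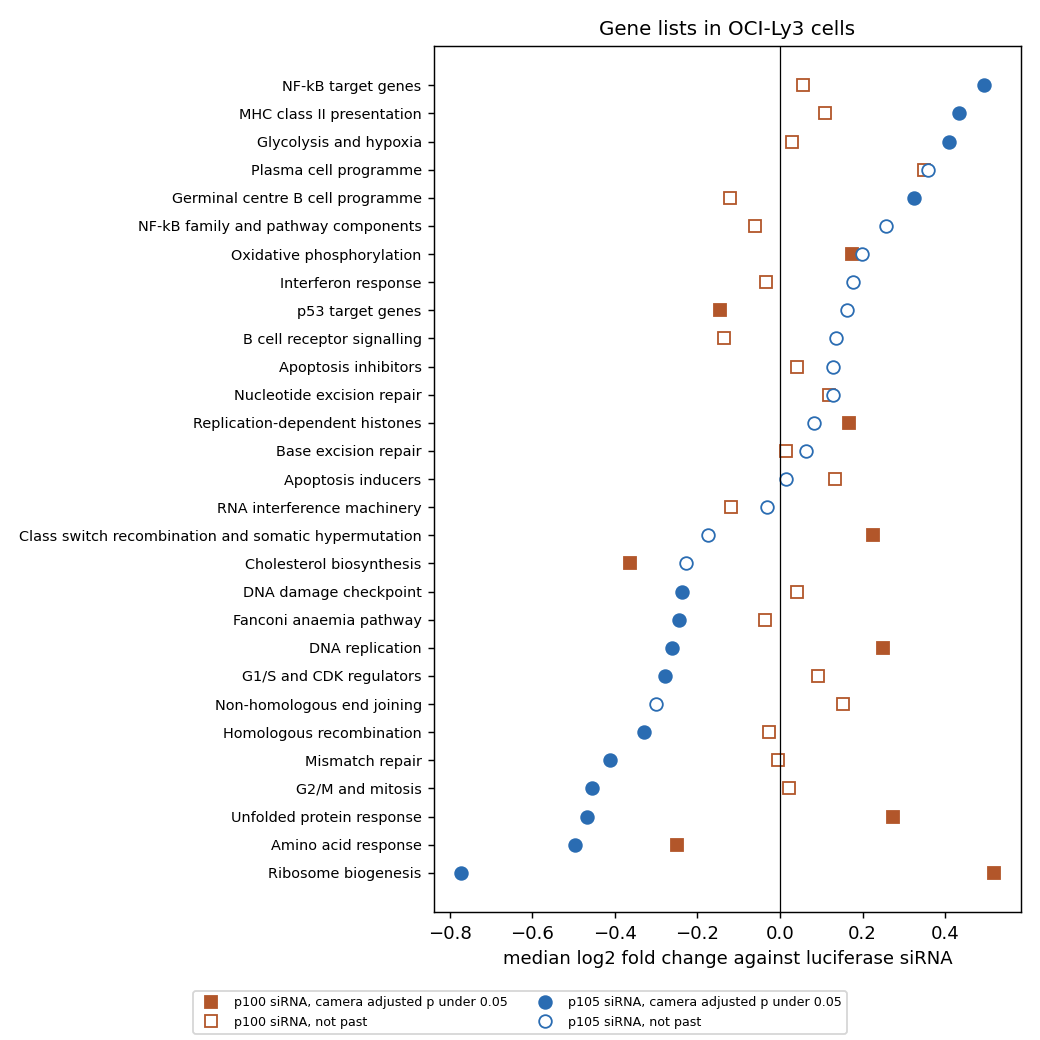
Median log2 change of the measured genes of 29 gene lists in OCI-Ly3 against luciferase siRNA, squares for p100-labelled and circles for p105-labelled arrays, filled where the camera adjusted p was under 0.05. Ribosome biogenesis lies at 0.52 on the p100-labelled and at -0.77 on the p105-labelled arrays, both filled.

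The contrast of the 2 siRNA labels with each other in OCI-Ly3 uses no luciferase array as reference. Ribosome biogenesis was higher on the p100-labelled than on the p105-labelled arrays, with 27 of 28 genes higher and 0 lower at an adjusted p under 0.05, also when adjusted over the list alone (median 1.21, camera adjusted p = 2.80e-14, adjusted p = 0.185 with an estimated correlation). DNA replication (24 of 36 higher, 1 lower, median 0.52, camera adjusted p = 6.41e-06, adjusted p = 0.344 with an estimated correlation) was higher as well, and so were G2/M genes (25 of 35 higher, 1 lower, median 0.52, camera adjusted p = 1.31e-05, adjusted p = 0.292 with an estimated correlation) and unfolded protein response genes (14 of 22 higher, 0 lower, median 0.80, camera adjusted p = 1.39e-05, adjusted p = 0.0623 with an estimated correlation). In these 3 lists too the counts adjusted over the list alone were the same. NF-kB targets were lower (3 of 36 higher, 13 lower, also when adjusted over the list alone, median -0.21, camera adjusted p = 0.0355, adjusted p = 0.558 with an estimated correlation). Several further lists passed at the same camera adjusted p of 0.0355. Homologous recombination had 18 of 34 genes higher and 5 lower (median 0.37, camera adjusted p = 0.0355, adjusted p = 0.558 with an estimated correlation). Mismatch repair had 7 of 15 higher and 2 lower (median 0.30, camera adjusted p = 0.0355, adjusted p = 0.499 with an estimated correlation). Checkpoint genes had 12 of 26 higher and 4 lower (median 0.32, camera adjusted p = 0.0355, adjusted p = 0.479 with an estimated correlation). Class switching had 12 of 20 higher and 3 lower (median 0.42, camera adjusted p = 0.0355, adjusted p = 0.425 with an estimated correlation). Among p53 targets 4 of 22 were higher and 11 lower (median -0.37, camera adjusted p = 0.0355, adjusted p = 0.392 with an estimated correlation). Among germinal centre genes 2 of 19 were higher and 9 lower (median -0.71, camera adjusted p = 0.0355, adjusted p = 0.351 with an estimated correlation). Glycolysis had 1 of 25 higher and 10 lower (median -0.26, camera adjusted p = 0.0355, adjusted p = 0.425 with an estimated correlation). Adjusted over the list alone the counts were the same, save 8 and 2 for mismatch repair and 5 and 12 for p53 targets. With slide as a block the last 3 had adjusted p = 0.0627, 0.106 and 0.106, the other 9 lists stayed past 0.05, and G1/S regulators passed as well (adjusted p = 0.00792). Myeloid markers had a median of -0.78 there (adjusted p = 0.0627), a value that rests on p100-labelled replicate 1. With dim markers included, that array lay 0.864 below the lower of its replicates in them. All block values of this contrast rest on that array in the same way, set against the 3 p105-labelled arrays of its slide. The lists that stayed past 0.05 with the block are therefore not separately checked by it.

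At 0.001, 1430 genes were higher and 1398 lower on the p100-labelled arrays, with SCHIP1 (at least 4.11-fold), NMI (4.14 ± 0.17, above background on 2 of 3 p105-labelled arrays), SPP1 (at least 7.01-fold) and SAMD9L (at least 3.52-fold) highest. Lowest were ALDOC (-5.13 ± 0.20), LAD1 (at least 6.45-fold), KLRC2 (at least 5.23-fold) and PSD2 (at least 4.36-fold), and the limma adjusted p of these 8 genes ran from 7.94e-06 to 6.61e-05. NFKB2 was lower by 1.45 log2 units on the p100-labelled arrays (log2 difference -1.45; adjusted p = 0.000782), and NFKB1 differed by 0.13 (adjusted p = 0.306). With slide as a block 198 genes passed, and within the slide that held 3 p105-labelled arrays and only p100 replicate 1, whose spread is taken from the other group, 0 passed 0.001 and 4076 passed 0.05. Log2 changes there correlated at r = 0.906 with those of all 6 arrays, of which these 4 are part. Each array left out also lowered the count of 2828, to between 1009 without p105 replicate 2 and 1733 without p100 replicate 3.

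In Daudi, replication-dependent histones and amino acid response genes were lower by camera with p100 siRNA than with luciferase siRNA. NFKB2 fell too, as it did with p105 siRNA. Camera passed 4 lists and fry 0. Of the 10 splits of the 6 arrays, the real one included, 5 passed at least as many lists by camera (highest other 9). Of 13 histone genes 3 fell and 0 rose (8 and 0 adjusted over the list alone, median -1.06, camera adjusted p = 5.44e-09, adjusted p = 0.611 with an estimated correlation). The falls were H4C3 (-2.86 ± 0.53), H2BC8 (-1.79 ± 0.35) and H2BC4 (-1.75 ± 0.37). Of 14 amino acid response genes 3 fell and 0 rose (4 and 0 adjusted over the list alone, median -0.61, camera adjusted p = 1.22e-05, adjusted p = 0.611 with an estimated correlation). The 3 were TRIB3 (-2.74 ± 0.50), CEBPB (-2.01 ± 0.39) and the mitochondrial folate enzyme MTHFD2 (at least 1.92-fold). Of 8 RNA interference genes 1 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.74, camera adjusted p = 0.0171, adjusted p = 0.709 with an estimated correlation). The gene that rose was the siRNA-processing nuclease DICER1 (1.89 ± 0.33). The interferon list passed with 0 of its 19 members past 0.05, also when adjusted over the list alone (median -0.42, camera adjusted p = 0.0171, adjusted p = 0.994 with an estimated correlation). NF-kB targets (1 of 29 rose, 0 fell, camera adjusted p = 0.940) and the NF-kB family (0 of 22 rose, 1 fell, camera adjusted p = 0.0765) did not pass. The unfolded protein response list, with 3 falls and 0 rises, did not pass either (camera adjusted p = 0.0765), and its median of 0.08 and its mean of -0.45 differed in sign.

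At 0.001, 20 genes rose and 15 fell in Daudi with p100 siRNA, and 305 passed 0.05, of which 200 rose. The groups did not overlap at 3577 genes (25.0%), against 10% by chance. The largest rises were ARPP21 (at least 5.16-fold), the focal adhesion gene TES (3.40 ± 0.37), the B-cell transcription factor BCL11A (3.38 ± 0.35), and the growth factor IGF1 (3.34 ± 0.41). They were followed by ZNF608 (at least 2.19-fold), the pseudogene GAS2L1P2 (2.90 ± 0.35), the transporter SLC12A3 (2.86 ± 0.35) and PARP8 (at least 3.62-fold). The largest falls were FBXL16 (at least 12.2-fold), NREP (at least 5.196-fold on that probe), SERPINF1 (-4.17 ± 0.33), and TTC39C (-3.43 ± 0.30, above background on 1 of 3 p100 arrays). They were followed, in fitted change, by the cohesin subunit RAD21 (at least 2.25-fold), GPR18 (at least 1.69-fold), MTHFD2 and the phosphatase PTPRE (-2.91 ± 0.32). Their limma adjusted p ran from 5.83e-07 for ARPP21 to 0.000966 for MTHFD2. Other scalings changed the split of rises and falls at 0.001: 14 and 24 with quantile normalization, 176 and 131 with the authors' values, 37 and 48 with the percentile over detected probes, and 79 and 88 with normexp without spots of high local background. With slide as a block 4 genes passed (1 rise, 3 falls), while within the slide that held 3 p100 arrays and 1 luciferase array, whose spread is taken from the p100 arrays, 120 passed. With the block, which rests on that 1 luciferase array, histones, amino acid response and RNA interference stayed past 0.05 and the interferon list had an adjusted p of 0.340. The unfolded protein response and glycolysis passed there as lower (adjusted p = 0.00363 for each) and base excision repair as higher (adjusted p = 0.0402). The count was 17, 20 and 22 without p100 replicates 1, 2 and 3, and 19 and 16 without luciferase replicates 1 and 2.

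With p105 siRNA in Daudi, more genes fell than rose in the main fit, though not with the authors' values (215 and 215 at 0.001). NFKB1 fell, and so did NFKB2. Neither was called different between the 2 siRNAs (limma adjusted p = 0.707 and 0.503). Of 80 ribosomal protein genes, a family chosen after its values were seen, 13 fell and 0 rose at 0.05, while 59 were higher and the median was 0.32. That sign depends on scaling: the median was -0.09 with quantile normalization (23 higher) and with the authors' values (24 higher). Among the largest falls of all genes were RPS29 (at least 35.3-fold on that probe), RPL39 (at least 15.3-fold) and RPS26 (-5.45 ± 0.56, above background on 1 of 3 p105 arrays). Next came the host gene SNHG29 (at least 23.4-fold on that probe), the initiation factor EIF3H (at least 15.7-fold), the chemokine receptor CXCR4 (at least 12.4-fold) and AHCY (at least 8.96-fold). Another probe of AHCY moved the other way past 0.05. Over the 258 genes that fell at 0.001, luciferase replicate 3 differed from the next luciferase array by a median of -1.16. The largest rises were ARPP21 (at least 12.7-fold), BCL11A (4.49 ± 0.35), ZNF608 (at least 3.34-fold), ARHGAP44 (3.64 ± 0.37), the selenium transporter SELENOP (3.42 ± 0.38), PARP8 (at least 5.18-fold), VTI1A (at least 4.27-fold on that probe) and AASS (at least 2.93-fold). The limma adjusted p of these genes ran from 9.47e-09 to 2.96e-05. Of 19 interferon response genes 9 fell and 0 rose (12 and 0 adjusted over the list alone, median -0.97, camera adjusted p = 0.00313, adjusted p = 0.945 with an estimated correlation). Among these were XAF1 (-2.01 ± 0.44), ISG20 (-1.69 ± 0.36), IFIH1 (-1.37 ± 0.30, above background on 1 of 3 p105 arrays) and MX2 (-1.35 ± 0.37). Of 20 glycolysis genes 6 fell and 0 rose (7 and 0 adjusted over the list alone, median -0.81, camera adjusted p = 0.00313, adjusted p = 0.945 with an estimated correlation). Its members past 0.05 included TPI1 (-2.26 ± 0.34), ALDOA (-1.78 ± 0.33), PFKL (-1.32 ± 0.31) and PGAM1 (at least 3.59-fold). Of 8 RNA interference genes 3 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.82, camera adjusted p = 0.0193, adjusted p = 0.945 with an estimated correlation). They were AGO4 (2.04 ± 0.40), DGCR8 (1.78 ± 0.36) and DICER1 (1.43 ± 0.33).

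NF-kB targets did not pass as a list in Daudi with p105 siRNA (4 of 29 rose and 7 fell, 5 and 9 adjusted over the list alone, camera adjusted p = 0.823). Members past 0.05 included CD86 at 2.10 ± 0.41, CCL17 at 1.53 ± 0.42, NFKBIA at -1.98 ± 0.32 and CD83 at -1.73 ± 0.46 (above background on 1 of 3 p105 arrays). The NF-kB family (1 of 22 rose, 5 fell, camera adjusted p = 0.823) and homologous recombination (2 of 16 rose, 5 fell, camera adjusted p = 0.700) did not pass either. At 0.001, 58 genes rose and 258 fell, and at 0.05, 1307 rose and 2141 fell. The groups did not overlap at 5340 genes (37.4%), against 10% by chance. The split at 0.001 was 215 and 215 with the authors' values, 10 and 26 with quantile normalization, 160 and 1000 with the percentile over detected probes, and 128 and 149 with normexp without spots of high local background. In that order 91, 33, 214 and 109 of the genes were shared with the main 316. Quantile normalization shifted the median log2 change of all genes to -0.18, and the percentile over detected probes shifted it to -0.26. No slide held Daudi p105 and luciferase arrays together, so no within-slide value could be had. A random block for slide, which cannot remove slide from these groups, gave 752 genes at an estimated correlation of -0.154. The count was 155 and 491 without p105 replicates 1 and 3, and 165 and 166 without luciferase replicates 1 and 2.

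Set against each other in Daudi, p100 siRNA left higher levels than p105 siRNA of SNHG29 (at least 12.4-fold), RPS29 (at least 18.5-fold) and RPL39 (at least 6.39-fold). It left lower levels of FBXL16 (at least 4.10-fold), GPR18 (at least 1.81-fold), the stress factor DDIT3 (-3.02 ± 0.31) and the kinase PIM2 (-2.95 ± 0.42). The limma adjusted p of these genes ran from 1.02e-05 to 0.000560. NFKB2 differed by -0.47 (adjusted p = 0.503) and NFKB1 by 0.26 (adjusted p = 0.707). In all 41 genes were higher and 10 lower at 0.001, and 0 gene lists passed (camera, smallest adjusted p = 0.0863). The split was 20 and 43 with the authors' values, 11 and 13 with the percentile over detected probes and 15 and 35 with normexp without spots of high local background, and quantile normalization gave 0 genes. No slide held both groups. The same random block gave 204 genes, and without p105 replicate 1 the count was 30. Another split of the 6 arrays also gave 51 genes.

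Within a line, the changes under the 2 siRNA labels were compared through their overlap. In OCI-Ly3 they ran against each other more often than together: at 0.05, 518 genes rose on the p100-labelled and fell on the p105-labelled arrays (170 for independent lists) and 487 did the reverse (235), while 106 rose (191) and 206 fell (209) on both. Fold changes correlated at r = -0.05 across genes, against 0.50 in simulations of unchanged groups that share simulated luciferase arrays. Their covariance was -0.01 against 0.04. In Daudi 162 genes rose (18.3 for independent lists) and 69 fell (15.7) with both siRNAs at 0.05, and 0 moved in opposite directions (30.0 and 9.60). At 0.001, 16 rose and 6 fell with both. The correlation was 0.76 against 0.49 simulated, and the covariance 0.40 against 0.07. Genes are not independent replicates, and since 3 control arrays cannot be halved, part of the excess may come from the shared controls. The simulations held no slide effect. In Daudi, luciferase replicates 2 and 3 lay alone on a slide, and a shift of that slide would move both comparisons the same way. The simulated values may therefore be too low to set beside those of Daudi.

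The lines were then compared for genes that changed under the same label in both, although in OCI-Ly3 neither target was called lower. Under the p105 label 3 genes passed 0.001 in the same direction in both lines. YPEL3 rose by 2.23 ± 0.20 in OCI-Ly3 and 2.09 ± 0.30 in Daudi (limma adjusted p = 0.000312 and 0.000165). The cell cycle transcription factor E2F2 fell by 0.90 ± 0.09 in OCI-Ly3 and at least 2.08-fold in Daudi (adjusted p = 0.000580 and 0.000248), and DKC1, which encodes the pseudouridine synthase dyskerin, changed by -0.81 ± 0.10 and -2.13 ± 0.36 (adjusted p = 0.000938 and 0.000711). Independent lists of the same lengths would share 3.99, 9 further genes passed in opposite directions, and Fisher's exact test of the overlap in any direction gave p = 0.215. At 0.05, 463 genes moved the same way (422 for independent lists) and 481 in opposite ways. Of the 463, 195 rose (209 for independent lists) and 268 fell (213). In any direction 944 were shared, against 885 for independent lists (Fisher's exact p = 0.00718, which takes genes as independent). Under the p100 label 0 genes passed 0.001 in both lines with limma, since 0 of the genes tested in both lines passed in OCI-Ly3 against 25 in Daudi, and the unadjusted p was under 0.05 at 5568 genes in OCI-Ly3 and 2317 in Daudi. At 0.05 it gave 37 genes, 32 rises and 5 falls, where independent lists would share 13.9, and 12 moved in opposite ways. In any direction 49 were shared, against 26.7 for independent lists (Fisher's exact p = 2.89e-05, with the same limit). Rises there included SRSF6 (1.06 ± 0.12 in OCI-Ly3 and 1.65 ± 0.37 in Daudi), UTP4 (0.85 ± 0.11 and 1.27 ± 0.32), the actin regulator WDR1 (0.73 ± 0.14 and 1.39 ± 0.32) and EIF6 (0.72 ± 0.11 and 1.47 ± 0.36). Falls included CTDSP2 (-0.88 ± 0.13 and -1.89 ± 0.40), GADD45A (-0.82 ± 0.14 and -1.57 ± 0.31) and the angiogenic factor VEGFA (-0.59 ± 0.11 and -2.36 ± 0.38). Since these genes passed only the looser level, they were named after their values were seen. Across all genes the log2 changes of the lines correlated at r = 0.07 for the p100 label and 0.05 for the p105 label. Without Daudi p105 replicate 3 the count of common p105 genes was 11, and it reached 0 without some other arrays.

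The difference between the lines in log2 change under the same label, which need not be the same knockdown, was tested directly. For the p100 label 19 genes passed 0.001, 7 with a higher and 12 with a lower log2 change in OCI-Ly3 than in Daudi, and for the p105 label 318, 233 higher and 85 lower. The largest fitted p100 differences were FBXL16 (4.65 ± 0.51), SERPINF1 (4.26 ± 0.45), TTC39C (4.17 ± 0.31) and NREP (4.03 ± 0.41) on the higher side. On the lower side were ARPP21 (-6.90 ± 0.51), ZNF608 (-3.91 ± 0.31), BCL11A (-3.64 ± 0.39) and TES (-3.34 ± 0.43). For the p105 label they were SNHG29 (7.06 ± 0.61), RPL39 (7.01 ± 0.65), RPS29 (6.60 ± 0.75) and EIF3H (6.54 ± 0.66), and on the lower side ARPP21 (-9.09 ± 0.51), SAMD9L (-4.71 ± 0.40), SAMSN1 (-4.58 ± 0.49) and ADGRA3 (-4.53 ± 0.49). The limma adjusted p of these genes ran from 7.18e-08 to 0.000782. Of these probes, 0 of 3 arrays were above background for FBXL16 and NREP in Daudi with p100 siRNA, for SNHG29, RPL39, RPS29 and EIF3H in Daudi with p105 siRNA, and for ARPP21 and ZNF608 in Daudi with luciferase siRNA. The same held for ARPP21, SAMD9L, SAMSN1 and ADGRA3 on the p105-labelled OCI-Ly3 arrays, and the last 3 were too dim to be tested in Daudi alone. The sizes and order of these differences are therefore fitted and rest on values near background. The split for the p105 label was 1195 and 903 with the authors' values and 817 and 817 with normexp without spots of high local background. For the p100 label it was 182 and 188, and 99 and 102, with these settings, 71 and 33 with quantile normalization and 53 and 36 with the percentile over detected probes. With slide as a block 0 genes passed for the p100 label and 510 for the p105 label, the latter from a random block that cannot remove slide, and a replicate block gave 3 and 82. Leaving out an array moved the p100 count to between 5 without OCI-Ly3 p100 replicate 3 and 22 without OCI-Ly3 p100 replicate 1, and the p105 count to between 136 without OCI-Ly3 luciferase replicate 1 and 722 without Daudi p105 replicate 3.

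**Figure D4:**
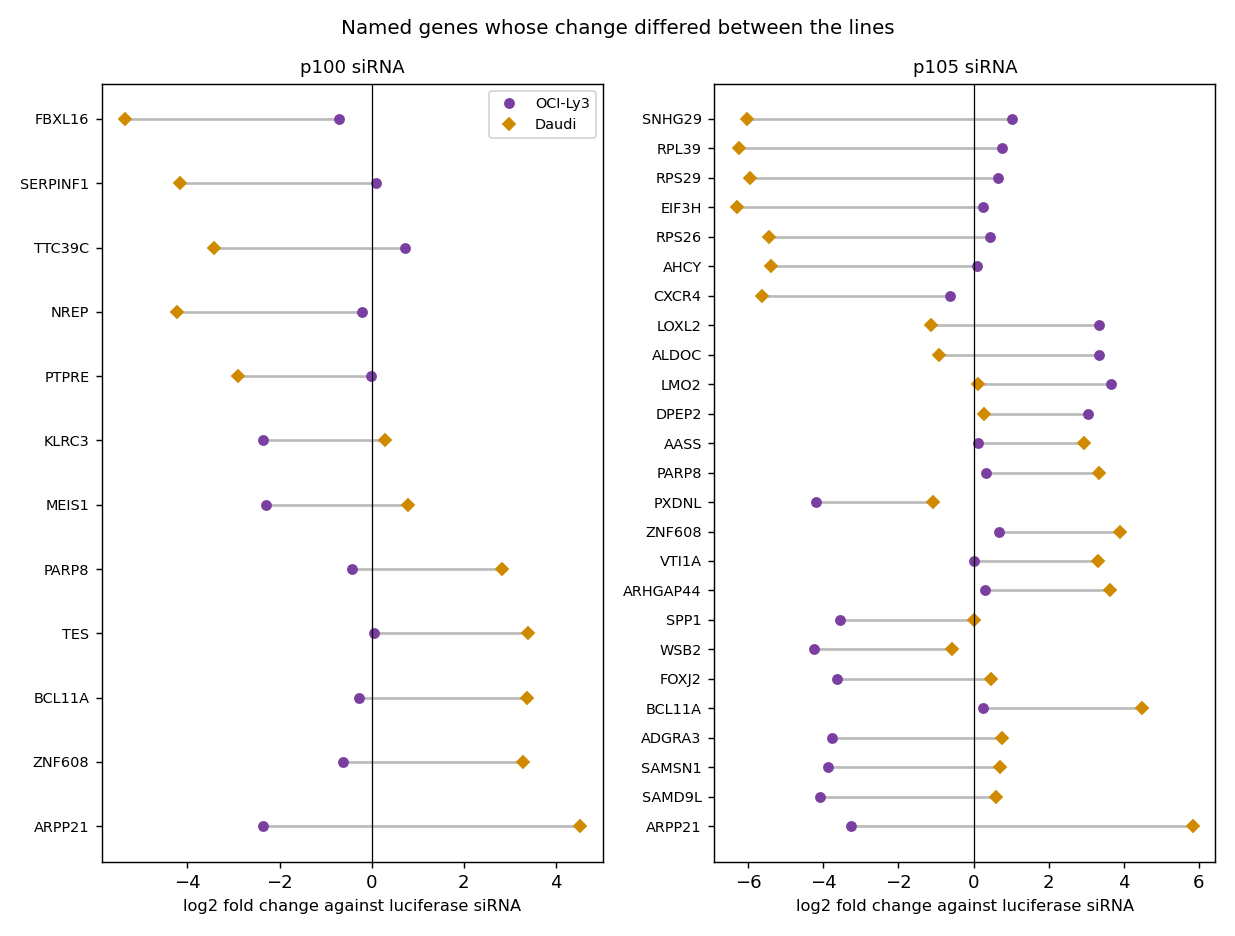
Log2 change against luciferase siRNA of the named genes whose change differed between the lines, circles for OCI-Ly3 and diamonds for Daudi, joined by a line for each gene and drawn for each siRNA. ARPP21 under the p105 label has fitted values of -3.25 in OCI-Ly3 and 5.83 in Daudi, but was above background on 0 of 3 p105-labelled OCI-Ly3 arrays and 0 of 3 Daudi luciferase arrays.

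Markers of other cell types did not pass in any comparison with luciferase siRNA without a slide block. With it, myeloid (adjusted p = 0.0173) and erythroid and platelet markers (adjusted p = 0.0172) were higher on the p105-labelled OCI-Ly3 arrays. That comparison runs through p100-labelled replicate 1, itself lower in both lists (0.864 and 0.712, dim markers included). Without the block the camera adjusted p in OCI-Ly3 was 0.892 and 0.274 for T-cell markers, 0.690 and 0.237 for myeloid markers, 0.670 and 0.283 for erythroid and platelet markers, and 0.690 and 0.633 for fibroblast and epithelial markers, on p100-labelled and p105-labelled arrays. In Daudi they lay between 0.823 and 0.991.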

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

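The tests of the slide and of single arrays at the end of this part were chosen after their values were seen.

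Arrays labelled with the same siRNA differed from luciferase arrays differently in the 2 lines, which a limma test of the difference marked out at 19 genes for the p100 label and 318 for the p105 label past an adjusted p of 0.001. Of these, 14 and 284 had fitted changes of opposite sign in the 2 lines, which choosing genes by their difference favours. In some the change in 1 line was near 0, so its sign says little. Examples in OCI-Ly3 and Daudi were SERPINF1 under the p100 label (0.10 and -4.17) and AHCY under the p105 label (0.10 and -5.40). In OCI-Ly3 neither target was called lower under its own label. For the p100 label the OCI-Ly3 minus Daudi difference of log2 changes was positive for FBXL16 (4.65), SERPINF1 (4.26), TTC39C (4.17), NREP (4.03) and PTPRE (2.89), all of which fell in Daudi. It was negative for ARPP21 (-6.90), ZNF608 (-3.91), BCL11A (-3.64), TES (-3.34) and PARP8 (-3.26), which rose in Daudi, and for MEIS1 (-3.08) and KLRC3 (-2.65), which fell in OCI-Ly3. Of 100 joint regroupings of both lines, the real one included, only the real one reached 19 genes for the p100 label (highest other 10). For the p105 label only the real one reached 318 (highest other 82), so 1 of 100 was as large each time. Regroupings mix arrays of different groups, so any difference between groups, from siRNA or slide, widens their spread and lowers their counts. The result therefore cannot tell an effect of the siRNA from one of the slide. The regroupings ignore slides, and with slide as a block 0 genes passed for the p100 label and 510 for the p105 label, the latter from a random block that cannot remove slide.

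For the p105 label the difference was positive for SNHG29 (7.06), RPL39 (7.01), RPS29 (6.60), EIF3H (6.54), RPS26 (5.90), AHCY (5.50) and CXCR4 (5.01), which fell in Daudi, and for LOXL2 (4.48), ALDOC (4.25), LMO2 (3.55) and DPEP2 (2.79), which rose in OCI-Ly3. It was negative for ARPP21 (-9.09), BCL11A (-4.24), ARHGAP44 (-3.34), VTI1A (-3.30), ZNF608 (-3.21), PARP8 (-3.01) and AASS (-2.82), which rose in Daudi. It was also negative for SAMD9L (-4.71), SAMSN1 (-4.58), ADGRA3 (-4.53), FOXJ2 (-4.11), WSB2 (-3.66), SPP1 (-3.56) and PXDNL (-3.11), which fell in OCI-Ly3. Several of these probes were below background in a group, so the differences are fitted values and not bounds.

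The 258 genes that fell in Daudi with p105 siRNA include abundant transcripts such as RPS29 and RPL39. Their median log2 level, relative to the 75th percentile, was -2.47, -2.69 and -2.47 on the p105 arrays, 1.39, 1.19 and -0.10 on the luciferase arrays, and -0.24, -0.24 and -0.50 on the p100 arrays. A slide effect stays open: OCI-Ly3 luciferase replicate 3, which shared the slide of the p105 arrays, differed from the other 2 luciferase arrays by -0.0271 over these genes, but it is 1 array of a line where they are much brighter. OCI-Ly3 RNA carried over into the Daudi luciferase arrays would bring its own profile, and the SD of the log2 ratio between the lines was 4.13 over these genes. A property of single arrays that varies within a group could contribute, since luciferase replicate 3 lay 1.16 below the next luciferase array over these genes (-1.16, against 0.148 over other genes). An effect of the siRNA stays open as well.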

How the results depend on the processing

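The percentile over detected probes, normexp without spots of high local background, the fits within slides and the slide block for lists were chosen after seeing the data. The cause of a change was not tested unless named. Counts are genes past an adjusted p of 0.001, in the order OCI-Ly3 p100, p105 and p100 against p105, Daudi p100, p105 and p100 against p105, then common p105 genes, then the difference between lines for p100 and p105, against 1, 732, 2828, 35, 316, 51, 3, 19 and 318. Common p100 genes stayed at 0 except at 0.05.

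An adjusted p under 0.05 gave 2517, 6607, 9019, 305, 3448, 360, 463, 184 and 3183, and 37 common p100 genes. Normexp gave 0 throughout, since up to 17 spots per array with a local background far above their signal widened the fitted background (SD 979 against 4.74 without them on 1 array). Without these spots it gave 98, 1991, 167, 13, 201 and 1634 for OCI-Ly3 p100 and p105, Daudi p100, common p105 genes and the line differences. With no filter on dim probes, which adds tests, counts were 0, 211, 1743, 0, 9, 0, 0, 8 and 208. Quantile normalization gave 1148 for OCI-Ly3 p105, 36 and 0 for Daudi p105 and the Daudi siRNA contrast, 1 common gene, and 104 and 649 line differences. The authors' values gave 99 and 2071 in OCI-Ly3, 307 for Daudi p100, 30 common genes, and 370 and 2098. The percentile over detected probes gave 85, 1160 and 24 in Daudi, 20 common genes, and 89 and 1242. Trended and robust moderation gave 68 and 1814 in OCI-Ly3, 53 for Daudi p100 and 23 common genes. The mean of a gene's probes and a fold of at least 1.5 changed no count by over 1.5 times. A single fit over 18 arrays gave 7, 151, 511, 84, 750, 115 and 6. The 6 arrays compared, which leave fewer degrees of freedom, gave 0, 81 and 904 in OCI-Ly3 and 485 and 109 for Daudi p105 and the Daudi contrast. The median log2 change over all genes was -0.23 for OCI-Ly3 p105 and 0.28 for the OCI-Ly3 contrast with normexp, -0.15 for Daudi p100 with the percentile over detected probes, and 0.19 and 0.22 for the Daudi contrast with quantile normalization and that percentile (0.11 with the values as reported).

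Slide as a block gave 2, 3, 198, 4, 752, 204, 0, 0 and 510, where 752, 204 and 510 come from a random block that cannot remove slide. Within single slides OCI-Ly3 p100 gave 0, the OCI-Ly3 contrast 0 and Daudi p100 120, the last 2 with an arm of 1 array. Replicate numbers do not pair the arrays: deviations from group means correlated at a median of 0.03 between same-number arrays in OCI-Ly3 (-0.38 to 0.49) and -0.14 in Daudi (-0.66 to 0.11), and 3 and 0 of 9 arrays correlated best with their own number. A replicate block gave 0, 31 and 995 in OCI-Ly3, 127 for the Daudi contrast, 1 common gene, and 3 and 82 line differences. A block for scan date was not run, as there was 1 date.

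Leaving out each array gave 0 to 8, 59 to 181, 1009 to 1733, 16 to 37, 155 to 491, 30 to 55, 0 to 11, 5 to 22 and 136 to 722. A group left with 2 arrays is assumed to vary like the others.

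Gene lists past 0.05 numbered 9, 14, 4 and 3 for OCI-Ly3 p100 and p105 and Daudi p100 and p105. All 4 counts were 0 with camera's estimated correlation. Fry gave 24 for OCI-Ly3 p105 and 0 for Daudi p100, normexp 1 and 0 in Daudi, and normexp without spots of high local background 2 for Daudi p100. For Daudi p105, no filter, the replicate block and the percentile over detected probes gave 5 each. Leaving out each array gave 6 to 9, 13 to 18, 3 to 7 and 2 to 5, with 7 and 5 in Daudi without luciferase replicate 3.

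Of 4018 alternative values for 215 named results, 2925 kept direction and side of the threshold, 1083 kept only their direction, 1 newly passed and 9 changed sign, none past 0.05 both times. With normexp these were TESMIN (-0.49), LAD1 (0.0401), KLRC2 (0.16), PSD2 (0.10), RAD21 (0.0165), MTHFD2 (0.0227), IFIH1 (0.0426) and E2F2 in Daudi (0.19), and with the mean of a gene's probes FANCC (-0.10). The tally says little about direction, since many of the 4018 values could not change sign. The single fit over 18 arrays, the 6 arrays compared, trended and robust moderation, and no filter keep the same group means. The replicate block is balanced, so its changes are the same where no value is missing. Leaving out an array cannot turn the sign of a gene whose groups do not overlap, which most naming rules required. Signal over background limits which spots can be measured, at 36.2% to 64.8% of spots well above it in Daudi and 64.3% to 73.5% in OCI-Ly3. Changes of 1 log2 unit were recovered in 0% of simulated genes in Daudi and 23.9% in OCI-Ly3. The simulations took each line's own residual spread, with a median SD of 0.41 in Daudi and 0.20 in OCI-Ly3. The cause of the wider spread in Daudi was not tested.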

Other observations

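The genes of the first 2 paragraphs, and the tests of the slide and of probe names, were chosen after their values were seen, and so was the second test of Daudi RNA, which followed a first one that decided nothing.

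No enrichment test was run for ribosomal protein genes. On the p105-labelled OCI-Ly3 arrays, of 80 measured, 64 rose and 0 fell at an adjusted p under 0.05, with a median log2 change of 0.53 and all 80 higher than with luciferase siRNA, while ribosome biogenesis factors fell. The number that rose was 18 with quantile normalization (median 0.14) and 20 with the authors' values (median 0.10), each with 61 of 80 higher, and it was 0 with slide as a block, with 78 higher. In Daudi with p105 siRNA 13 of the 80 fell and 0 rose, 10 of them past 0.001, while the median was 0.32 and 59 were higher. That median was -0.09 with quantile normalization and with the authors' values.

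Genes past 0.05 under the p105 label in both lines included, in OCI-Ly3 and Daudi, the cell cycle inhibitor CDKN1B (1.36 and 1.37), the phosphatase PTPN6 (2.03 and 1.47), the splicing factor SRSF5 (1.26 and 1.34), GDF11 (1.78 and 1.49) and SCRN2 (1.63 and 1.63). Lower in both were the succinate dehydrogenase assembly factor SDHAF3 (-3.36 and -2.03), the tyrosine kinase FES (-2.12 and -1.51), S100A10 (-2.90 and -1.26) and SAMD9 (-1.25 and -1.35). Shared rises numbered 195, fewer than the 209 for independent lists, and shared falls 268 against 213, while 481 genes moved in opposite ways. These genes are therefore examples and do not show a common response.

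Replicate 1 of the OCI-Ly3 p100 group lay at least 8-fold below both other replicates at 19 genes, including CT45A5, CD44, CCND2, SRGN, IL1R2 and CCR7, and above them at 1, TUFT1. Such gaps were not particular to this array. Daudi p105 replicate 3 lay that far below both its replicates at 29 of 14297 genes, and Daudi p100 replicate 3 above both at 12. Causes were examined only for the OCI-Ly3 array. The median over the 19 genes was -5.61 in replicate 1, -1.28 and -1.34 in replicates 2 and 3, and between -5.09 and -4.26 on the luciferase and p105-labelled arrays. The slide is argued against by luciferase replicates 1 and 2, which shared it with p100 replicates 2 and 3 and lay only 0.418 above luciferase replicate 3, and a wrongly labelled luciferase array by the 94.2% of 1575 genes at which replicate 1 lay beyond all luciferase arrays in the direction of the other 2 p100 arrays (54.9%, 46.5% and 63.1% for luciferase arrays left out in turn). Daudi RNA in replicates 2 and 3 would raise all genes bright in Daudi, but 841 genes at least 16-fold brighter there rose by a median of 0.179 (quartiles -0.104 and 0.576), and the first test, the Daudi level minus that of the lower replicate over the 19 genes, gave 0.162. RNA of another cell type stays open, as the highest of the 4 marker list medians was 0.864, for myeloid markers. That median includes dim probes, since 6 of 16 myeloid markers were well above background on all OCI-Ly3 arrays. Replicate 1 also had fewer spots well above background (65.6%) than replicates 2 and 3 (70.9% and 72.4%). No biological explanation was tested.

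Probes of the same gene ranked less alike on the Daudi than on the OCI-Ly3 arrays: over 6707 pairs Spearman's rho was 0.236 in Daudi. Wrong probe names would lower it in both lines, and it was 0.642 in OCI-Ly3. Low signal as the whole cause is argued against by pairs with 1 bright probe, of which 52.4% of 613 in Daudi had the other probe well above background on all 9 arrays, against 91.8% of 2200 in OCI-Ly3. It stays open as a part, since over pairs with both probes above background rho was 0.304 in Daudi (1068 pairs) and 0.435 in OCI-Ly3 (3914 pairs), closer than over all pairs. Shortened transcripts would favour the 3' probe in Daudi. But that probe was relatively brighter there in only 29.6% of 2233 pairs (95% exact interval 27.8% to 31.6%). In these pairs the 3' probe was the brighter in 67.7% in OCI-Ly3 and in 38.0% in Daudi. The median shift of the 3' probe relative to the other, Daudi against OCI-Ly3, was -2.22 log2 units. Probe position therefore went with the difference between the lines, opposite to shortened transcripts, and the cause of this shift was not tested. No biological explanation was tested, and Daudi values rest on single probes whose relation to other probes of the gene is loose.

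With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave the most genes past 0.001, as the only 1 of 10, for OCI-Ly3 p100 (1, highest other 0), OCI-Ly3 p105 (732, highest other 0), the contrast of the siRNA labels in OCI-Ly3 (2828, highest other 0), Daudi p100 (35, highest other 0) and Daudi p105 (316, highest other 0). In the contrast of the siRNAs in Daudi 2 splits gave 51. The other one sets p100 replicates 1 and 2 and p105 replicate 3, with 36.2% to 40.9% of spots well above background, against the other 3 arrays, with 49.4% to 64.8%, and it does not follow the slides. For gene lists, as many passed in 3 splits for OCI-Ly3 p100 (9, highest other 15), 1 for OCI-Ly3 p105 (14, highest other 13), 5 for Daudi p100 (4, highest other 9) and 2 for Daudi p105 (3, highest other 3). Of 100 joint regroupings of both lines, 1 gave as many common p105 genes (3, highest other 0) and all 100 as many common p100 genes (0, highest other 0). Neither decides anything, since other splits against luciferase called 0 genes in either line and had none to share, and 0 is always reached. For the p105 label independent lists would share 3.99 genes.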
